A study of Arabidopsis thaliana with 12 samples.

How the data were processed

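RNA was sequenced from 11-day-old seedlings of Arabidopsis thaliana, accession Columbia, in 12 libraries that the labels place in 6 groups of 2. The groups were untreated wild type, the UPF1 mutant lba1, the UPF3 mutant upf3-1, lba1 upf3-1 with both mutations, wild type kept in liquid medium for 4 h (mock), and wild type kept for 4 h in the same medium with cycloheximide at 10 µg/ml. Per the labels' protocols, seedlings grew under continuous light on medium with 2% sucrose, and libraries were made from total RNA with an Illumina TruSeq RNA kit, which enriches polyadenylated RNA and does not mark the strand of a transcript.

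The authors deposited gene expression as RPKM (reads per kilobase of gene, scaled to the total of the column) for 33602 loci, with 1 column for each of the 6 groups. The genome build was TAIR10, per the submitters' processing notes. The aligner, the counting rules, the gene lengths and the way in which the libraries of a group became 1 column are not given in the sources used here. Of the loci, 3987 were at 0 in all 6 columns. Names, gene classes, approximate exon lengths and overlaps with other loci were taken from the TAIR10.1 reference annotation, in which 32835 of the locus codes were found and 767 were not, 279 of these on the organelle genomes. No coordinates were taken from it.

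Depth was estimated from 623 transfer RNA loci, which are short and of simple structure. In each column their low values, up to 8 reads, multiplied by gene length were whole multiples of a single step, the pattern left where whole reads of 1 pool are divided by 1 total. Between 91.9% (cycloheximide) and 97.3% (lba1 upf3-1 and mock) of the values used were whole within 0.05 of a read plus the rounding of the file to 3 decimals. The steps implied totals of 83.1 M reads for wild type, 88.2 for lba1, 91.5 for upf3-1, 89.2 for lba1 upf3-1, 87.5 for mock and 84.9 for cycloheximide. A gene of 1 kb at 5 RPKM then rests on 416 to 458 reads. Its exact Poisson 95% interval runs from −9.38% to 10.1% in wild type, the shallowest column, and from −8.95% to 9.59% in upf3-1, the deepest. A count of 3 reads, used as the floor for a gene at 0, corresponds to 0.0328 to 0.0361 RPKM at 1 kb. Such intervals and floors cover counting error only. Over the 383 named genes with a mean of at least 5 RPKM, the 95% counting interval of a log2 difference, given as plus or minus, had a median of 0.08 and a 95th percentile of 0.26.

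The plan made before the data were examined was a limma fit over 12 libraries, with camera and fry for gene lists and Fisher's exact test for overlaps and gene classes. The fit, camera and fry could not be run on 1 column per group, because no spread between replicates can be estimated. Fisher's test was planned on the genes called by that fit and was not run on the genes past 2-fold, since genes are not independent of one another. Numbers for independent lists and random sets stand in its place. The plan named the substitute for that case. Differences were computed on log2(RPKM + 0.5), a scale that understates the change of low genes, for the 14079 genes with a mean of at least 5 RPKM over the 6 columns. A gene is described as higher or lower where its columns differ by at least 2-fold on that scale, a rule of size and not a test. The comparisons were each mutant against wild type, cycloheximide against mock, mock against wild type, the mutants against one another, and the difference between the cycloheximide effect and the lba1 upf3-1 effect.

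Named genes were the members of the NMD and exon junction complex list, the 8 highest and 8 lowest genes of each mutant against wild type and of cycloheximide against mock, the 5 highest and 5 lowest of the other contrasts, and the 6 highest and 6 lowest shared by lba1 upf3-1 and cycloheximide. For each list and main comparison, up to 4 members past 2-fold were taken, or 2 where none was. Some were left out for length, never by value, and a few are not reported here. The genes named as higher or lower in all 3 mutants, the gene classes beyond coding, non-coding and pseudogene, and the seed, iron and phosphate lists were chosen after the data were seen.

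A total of 17 lists with 335 genes was fixed before the data were examined. They cover NMD and exon junction complex factors, conserved uORF genes (mRNAs with a conserved upstream open reading frame), splicing regulators, salicylic acid defence, NLR immune receptors, early auxin genes, early stress and wound transcription factors, jasmonate signalling, cytosolic ribosomal proteins, ribosome biogenesis, photosynthesis, root tissue markers, the circadian clock, endoplasmic reticulum stress, heat shock, hypoxia and the cell cycle. The list of early stress and wound transcription factors also holds the touch genes CML24, CML12 and TCH4. That of splicing regulators also holds TFIIIA, a transcription factor gene. Members with a mean of at least 0.5 RPKM (312 of the 335) counted as measured. The median of each list was set against the medians of 10000 random lists of the same size matched on mean expression in 20 bins. The range given beside a median runs from percentile 2.5 to percentile 97.5 of the random lists, so that about 5% of lists of unrelated genes lie outside it. Members of a list that are regulated together can shift together, and the ranges do not allow for this. The setting against random lists describes these columns and says nothing about the spread between seedlings.

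Comparisons against the same wild type column share its chance error. Unchanged groups were therefore simulated 20 times with Poisson noise in the reads, and the correlation and covariance of their log2 differences stand beside the observed ones. That simulation holds no variation between seedlings. The number of shared genes is given with the number that independent lists of the same sizes would share. The size rule was tested on simulated data for lba1 against wild type over 14013 genes. It took none of 50 genes set to a 1.5-fold change, all 50 at each of 2.5-, 3- and 4-fold, and 0 of 13813 unchanged genes. The simulated columns held counting error only, so this shows that the computation works and not that the rule holds between seedlings.

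Alternatives were pseudocounts of 0.1 and 1 RPKM, no filter or a filter at 2 RPKM, median scaling and quantile normalization. Filters at 0.5 and 20 RPKM, a 4-fold rule, and the list medians at a pseudocount of 0.1 and under quantile normalization were added after the data were seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Alternative splicing, which the series also covers, was not analysed here.

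Values of close paralogs such as the RBCS and LHCB1 genes, SAUR19 to SAUR24, the small heat shock genes and the CBF genes are uncertain, because reads can be split between copies. The same holds for genes that overlap another locus, since the libraries do not mark the strand and the counting rules are not given. Of the exon bases of RPS2 and ERF105, 100.0% lie under another locus, with 98.5% for MYC2, 90.5% for CHS1, 55.0% for AT3G06019, 40.6% for LHCB2.3, 39.6% for IAA3, 35.7% for BHLH38, 33.5% for KNOLLE, 29.5% for COR15B and 20.5% for AT2G30766. A total of 52 loci had values identical to those of another locus in all 6 columns.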

Results

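Transcript levels were measured in whole seedlings of Arabidopsis thaliana to compare plants with intact and impaired nonsense-mediated decay (NMD), the pathway that degrades mRNAs with early stop codons and related features. UPF1, altered in lba1, is the RNA helicase at the core of the pathway, and UPF3, disrupted in upf3-1, is one of its partners. Cycloheximide blocks translation, on which NMD depends, and mock seedlings received the same liquid incubation without it. The 12 libraries form 6 groups of 2 and are represented by 1 RPKM column per group, with implied depths of 83.1 to 91.5 M reads. The differences therefore have no replicate check, and neither an SD nor a p-value can be attached to them.

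UPF3 was at 4.95 RPKM in upf3-1 and 4.82 in lba1 upf3-1, against 13.1 in wild type, 22.2 in lba1, 25.4 in mock and 23.1 with cycloheximide. On the log2 scale it was lower by the 2-fold rule in both columns labelled upf3-1, at −1.32 and −1.35, each plus or minus 0.10 from counting error. UPF1 was at 20.7 RPKM in wild type, 24.0 in lba1, 24.6 in upf3-1, 24.7 in lba1 upf3-1, 29.4 in mock and 19.2 with cycloheximide. Because lba1 is a point mutation, the UPF1 transcript level does not check that label.

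**Figure D1:**
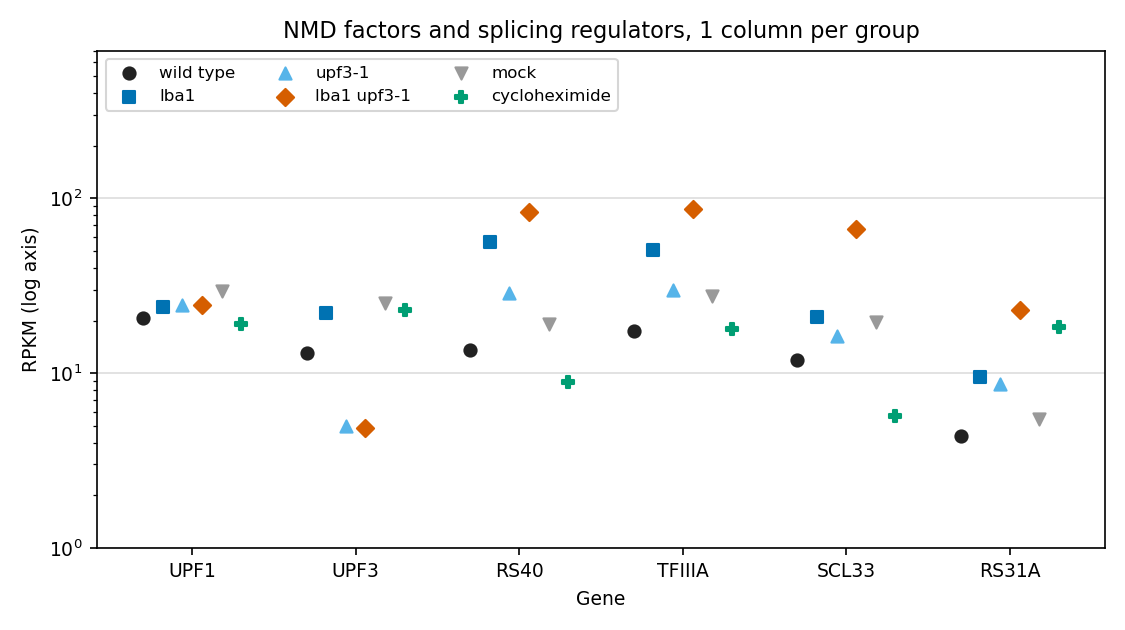
RPKM on a log axis of 6 genes (UPF1, UPF3 and the splicing-linked genes RS40, TFIIIA, SCL33 and RS31A) in the 6 columns, 1 point per gene and column, without error bars because each group has 1 column. UPF3 is lowest in the columns labelled upf3-1, and RS40 is at 83.3 RPKM in lba1 upf3-1 and 13.5 in wild type.

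Across the 14079 genes described, the single mutants resembled wild type, with Pearson's r of 0.94 for lba1 and 0.96 for upf3-1 and 0.94 between them. The lba1 upf3-1 column stood apart from wild type, at r = 0.45, and so did cycloheximide, at 0.13, while mock reached 0.75. The cycloheximide column had r = 0.45 with mock. These correlations are across genes, which are not independent replicates. The 100 most abundant loci held 22.7% of summed RPKM in wild type, 20.9% in lba1 upf3-1, 16.5% in mock and 26.9% with cycloheximide, and the median of the described genes was 7.78 RPKM with cycloheximide and 13.2 in mock.

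In lba1, the medians of salicylic acid defence genes and early stress transcription factors were lower than in wild type, and those of early auxin, photosynthesis and splicing regulator genes were higher. PR1, the standard marker of salicylic acid defence, was at 0.922 RPKM in lba1 and 113 in wild type, a log2 difference of −6.32. BAM5, the sugar-inducible beta-amylase whose low level gave lba1 its name, was at 0.983 against 59.2 RPKM (−5.33). The defensin genes PDF1.2 and PDF1.2c followed at −4.06 and −3.27. In all, 672 genes were at least 2-fold higher and 272 at least 2-fold lower, together 6.71% of those described.

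The other genes among the 8 lowest in lba1 were IPS1, a transcript induced by phosphate starvation (−3.99), NAS3, a nicotianamine synthase (−3.56), ELI3-2 (−3.38) and TAT3, a wound-inducible aminotransferase (−3.03). The largest positive differences belonged to AT1G68250 (21.0 against 0.178 RPKM, 4.98) and the small heat shock gene HSP17.4 (16.3 against 0.723 RPKM, 3.78). SESA1, a seed storage albumin gene, was at 4.50 RPKM in lba1 and rested on about 1 read in wild type, with a log2 difference of 3.28 plus or minus 0.18 from counting error. ASN1, an asparagine synthetase gene induced by low sugar and darkness, was at 51.7 against 7.21 RPKM. The non-coding RNA AT3G26612 (2.74), AT2G37030 (2.70), the inositol oxygenase gene MIOX2 (2.67) and the fatty acyl reductase gene FAR1 (2.66) completed the highest 8.

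Of the 24 salicylic acid defence genes, 16 were lower by the 2-fold rule and 0 higher, and their median of −1.39 lay below all 10000 random lists (range −0.17 to 0.21). PR2, a glucanase gene, was at −2.49, PNP-A at −2.37 and the wall-associated kinase gene WAK1 at −2.05. Among the early stress and wound transcription factors 11 of 22 were lower and 0 higher, with a median of −0.99 below every random list (range −0.37 to 0.08). ZAT10 was at −2.09, WRKY33 at −1.82 and WRKY40 at −1.80, and ERF105, which lies wholly under another locus, at −2.07. NLR immune receptors had 0 higher and 0 lower genes of 27 and a median of −0.12 (range −0.09 to 0.26), with ADR1 at −0.86. Jasmonate signalling genes had a median of −0.14, inside the range of −0.37 to 0.11, with 3 of 19 lower, among them LOX4 (−1.69) and LOX2 (−1.22).

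Early auxin genes had 8 of 24 members higher and a median of 0.82, above all random lists (range −0.09 to 0.28). The Aux/IAA genes IAA29 (2.34), IAA3 (2.06), IAA4 (1.57) and IAA19 (1.37) were higher, IAA3 with 39.6% of its exon bases under another locus. Photosynthesis genes had 10 of 30 higher and 0 lower, or 6 and 2 after median scaling, with a median of 0.47 above all random lists (range −0.43 to −0.06). LHCB1.4 reached 1181 against 359 RPKM and LHCB2.3 424 against 152, whereas the Rubisco small subunit genes RBCS2B (−0.95) and RBCS1B (−0.92) were below wild type.

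Splicing regulators, many of which make splice variants that NMD degrades, had 3 of 30 higher and a median of 0.39, above all random lists (range −0.11 to 0.22). RS40 was at 56.1 against 13.5 RPKM, RS31A at 9.53 against 4.35 and TFIIIA, a transcription factor gene on the list, at 50.9 against 17.5. Only 20 of the 42 conserved uORF genes were measured, so the values of this list describe that part alone in every comparison. Of the 20, 6 were higher, with a median of 0.47 (range −0.07 to 0.35). AT5G45430 was at 1.79, the phosphoethanolamine methyltransferase gene XPL1 at 1.59 and SACL3 at 1.24. The NMD and exon junction complex list had a median of 0.31, inside its range of −0.23 to 0.35.

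Cytosolic ribosomal protein genes lay at −0.49 (range −0.37 to 0.03), with 27 of 28 below wild type and none past 2-fold, and ribosome biogenesis genes at −0.55 (range −0.35 to 0.33), NOP58-1 among them at −0.68. Heat shock genes had 4 of 12 higher and a median of 0.64 (range −0.16 to 0.36), from HSP17.4 at 3.78 to HSP70 at −0.86. Root tissue markers (0.54, range −0.07 to 0.43) and clock genes (0.39, range −0.15 to 0.29) were above their random lists, with CASP5 at 1.11 and PRR7 at 1.29. Hypoxia genes (−0.43, range −0.20 to 0.39) and cell cycle genes (−0.19, range −0.16 to 0.63) were below theirs, with no member past 2-fold. Endoplasmic reticulum stress genes were inside theirs, with a median of 0.01, a mean of −0.06 and a median of −0.14 after median scaling. In total 14 of the 17 lists lay outside their range. Median scaling removed a shift of 0.15 from this comparison and changed the numbers of higher and lower genes to 469 and 393, or from 71.2% to 54.4% higher, with 62.2% under quantile normalization.

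In upf3-1, the medians of ribosome biogenesis and cell cycle genes were lower than in wild type, and that of early stress transcription factors was higher. The iron deficiency median was lower too, but that list was drawn up after its leading genes had been noticed. Its 7 members not seen when listed had a median of −0.59. The iron-responsive bHLH factors BHLH100, BHLH38 and BHLH39 were at 3.89, 3.18 and 3.16 RPKM, against 40.4, 30.7 and 22.2 in wild type (log2 −3.22, −3.08 and −2.63). BHLH38 has 35.7% of its exon bases under another locus. AT1G47395 and AT1G47400, which encode peptides of the iron deficiency response, were at −2.34 and −2.15. By the 2-fold rule 536 genes were higher and 77 lower, 4.35% of those described.

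AT2G14247 (−1.98), the defensin-like gene AT1G13609 (−1.84) and PDF1.2 (21.8 against 78.4 RPKM) completed the 8 lowest. The highest was the calmodulin-like gene CML38, at 25.6 against 2.94 RPKM (2.92). It was followed by AT4G15260, at 61.3 against 7.96 RPKM, by ACS11, a gene of ethylene synthesis (2.74), and by AT2G29170 (2.72) and AT3G45443 (2.70). The other places went to the non-coding RNAs AT3G26612 (2.72), AT1G11175 (2.71) and AT5G38005 (2.64), each also higher in lba1.

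Early stress and wound transcription factors had 12 of 22 members higher and 0 lower, with a median of 1.03 above all random lists (range −0.15 to 0.35). ERF6 was at 2.06, WRKY18 at 2.04, ERF11 at 1.85 and ERF105 at 1.83. Jasmonate signalling genes had a median of 0.60 (range −0.15 to 0.36), with 5 of 19 higher, among them JAZ7 (2.05), LOX4 (1.64) and VSP1 (1.39), and PDF1.2 lower. Early auxin genes had 5 of 24 higher (median 0.51, range −0.14 to 0.24), with IAA3 at 1.68, SAUR19 at 1.26, IAA6 at 1.17 and IAA2 at 1.15. Conserved uORF genes had 3 of 20 higher (median 0.31, range −0.16 to 0.24), which became 0.00 under quantile normalization, with AT5G45430 at 1.60, XPL1 at 1.11 and CIPK6, a kinase gene, at 338 against 155 RPKM. The clock list had a median of 0.39 (range −0.16 to 0.28) and PRR9 at 1.11.

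Ribosomal protein genes had a median of −0.49, below all random lists (range −0.10 to 0.35), with 27 of 28 below wild type and none past 2-fold, RPL10B at −0.70 being an example. Ribosome biogenesis genes lay at −0.73, also below all random lists (range −0.23 to 0.42), with FIB2, a fibrillarin gene, at −1.22 and NOP58-1 at −1.02. Cell cycle genes lay at −0.78 (range −0.32 to 0.41), with the mitotic cyclin gene CYCB1;2 at −1.01. Medians inside their ranges were those of salicylic acid defence (0.22, with WRKY46 at 1.31 and PAD4 at 1.09), NLR receptors (0.23), photosynthesis (0.36, with LHCB1.2 at 1.16), endoplasmic reticulum stress (−0.17), heat shock (−0.11) and hypoxia (−0.20, with SUS4 at −1.27 and PDC1 at −1.17). The medians of the NMD list (0.04), splicing regulators (0.05, with RS40 at 1.06) and root markers (0.04) were also inside, and each changed sign with median scaling, to −0.02. In all 8 of the 17 lists were outside. Quantile normalization gave 459 higher and 167 lower genes, or 73.3% higher in place of 87.4%.

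In a direct comparison of the single mutants, BAM5 (−6.69) and PR1 (−5.32) had the largest negative differences of lba1 from upf3-1, followed by DIC2, a mitochondrial carrier gene (2.52 against 56.6 RPKM), the acetyltransferase gene NATA1 (−4.20) and PDF1.2b (−3.96). The largest positive ones were AT1G68250 (4.28), HSP17.4 (3.73), CRU3, a cruciferin seed storage gene (27.1 against 1.64 RPKM), SESA1 (3.04) and HSP17.6C (2.93). Of the described genes 133 were at least 2-fold higher in lba1 than in upf3-1 and 540 lower.

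A total of 261 genes were at least 2-fold higher in both lba1 and upf3-1, where independent lists would share 25.6, and 13 were lower in both, where they would share 1.49. A further 36 genes were lower in lba1 and higher in upf3-1 (10.4 for independent lists), and 1 went the opposite way (3.68). The log2 differences of both mutants had r = 0.47 and rho = 0.53 across genes. Unchanged groups simulated against the same wild type column gave r = 0.519 but a covariance of 0.00175, against 0.116 observed. How much of the excess comes from variation in the shared wild type column cannot be told, because the simulation holds counting error only. The numbers for independent lists do not allow for that column either.

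With both mutations present, photosynthesis genes were lower without exception, and most salicylic acid defence, heat shock and hypoxia genes were higher. RBCS2B was at 33.7 RPKM against 4427 in wild type (log2 −7.02), and CA1, the chloroplast carbonic anhydrase gene, at 7.78 against 1223 (−7.21). PR1 was at 6294 against 113 RPKM (5.80), the opposite direction to lba1 alone. HSP17.4 was at 182 against 0.723 RPKM (7.22). Of the described genes 3105 were higher and 2988 lower, together 43.3%, with 1221 and 1466 past 4-fold. Median scaling gave 2704 higher and 3285 lower and quantile normalization 2922 and 3029, so which direction held more genes turned with the scaling.

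The lowest gene on the log2(RPKM + 0.5) scale, which compresses genes at or near 0, was FBA5, a fructose-bisphosphate aldolase gene, at 0.251 against 177 RPKM (−7.88). AT2G10940 (−7.30), the germin-like gene GER3 (−6.91), the inositol phosphate synthase gene MIPS1 (−6.80) and RBCS1B (−6.65) were close to it. PDF1.2 was at 0 in lba1 upf3-1 and, by a floor of 3 reads in that column, at least 1351-fold lower than in wild type. The highest was ADPG1, a polygalacturonase gene of organ separation, at 174 RPKM against 0.066 in wild type, 0.005 in lba1 and 0.306 in upf3-1 (8.26 from wild type). Next were the defensin gene LCR67 (94.5 RPKM), the glutathione transferase gene GSTU3 (292 RPKM) and HSP17.6A (119 RPKM), with log2 differences of 7.39, 7.33 and 6.95. The trypsin inhibitor genes TI1 and KTI1 were at 2803 and 2488 RPKM against 22.2 and 22.4, and AT3G02480 was at 6.91.

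All 30 photosynthesis genes were at least 2-fold lower, with a median of −4.02 below every random list (range −0.92 to 0.70). RBCS3B was at −6.62 and LHCB2.3 at −5.41. The 43 chloroplast-encoded genes among those described were all lower too, at a median of −1.71, although the library protocol enriches polyadenylated RNA and so samples chloroplast transcripts poorly. Early auxin genes had 17 of 24 lower and 4 higher and a median of −1.88, below every random list (range −0.61 to 0.64). SAUR14 (−4.33), SAUR24 (−3.79) and SAUR20 (−3.61) were lower, whereas GH3.5, which conjugates auxin to amino acids, was higher (124 against 8.89 RPKM). Root tissue markers had 9 of 14 lower (median −1.60, range −0.90 to 0.76), with the root hair expansin gene EXPA7 at −2.45 and CASP1 of the root endodermis at −2.39. All 6 cell cycle genes were lower (median −1.88, range −1.29 to 1.15), with CYCB1;2 at −2.78 and KNOLLE at −2.60.

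Salicylic acid defence genes had 19 of 24 higher and 0 lower, with a median of 2.29 above every random list (range −0.64 to 0.69). WRKY38 was at 62.3 against 0.998 RPKM, FMO1 at 87.4 against 2.84 and PNP-A at 4.72. Of the heat shock genes 10 of 12 were higher, at a median of 4.65 above every random list (range −0.81 to 0.86), and HSP17.6II and HSP17.6C were at 6.64 and 5.18. Hypoxia genes had 8 of 11 higher (median 2.02, range −0.89 to 0.95), with the haemoglobin gene HB1 at 484 against 41.2 RPKM and the alcohol dehydrogenase gene ADH1 at 272 against 38.9. Splicing regulators had 14 of 30 higher and 1 lower (median 0.72, range −0.43 to 0.60). RS40 (83.3 RPKM), SCL33 (66.4), the transcription factor gene TFIIIA (87.3) and RS31A (23.0) were at log2 differences of 2.58, 2.43, 2.29 and 2.28.

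The other 9 lists lay inside their ranges. The 20 measured of the 42 conserved uORF genes had a median of 0.41 with 6 higher and 2 lower. YSL3 at 2.18 and the methyltransferase gene NMT3 at −3.44 were at either end. Jasmonate signalling genes went both ways, with 7 higher and 8 lower (median −0.10), from JAZ8 (3.52) and JAZ7 (3.26) to AOC2 (−3.11) and PDF1.2. Early stress factors had 10 higher (median 0.60), with ZAT12 at 3.07 and WRKY18 at 3.00. NLR receptors had 7 higher and 1 lower (median 0.20), with ADR1 at 1.90 and NRG1.2 at 1.24. Medians were 0.20 for the NMD list, −0.63 for ribosomal proteins with 4 lower, −0.71 for ribosome biogenesis, −0.22 for the clock and 0.45 for endoplasmic reticulum stress. BZIP60, a regulator of the unfolded protein response, was at 2.39, and the clock genes CHE and RVE1 at −2.24 and −2.07. Median scaling removed a shift of 0.14 here.

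Against each single mutant the lba1 upf3-1 column differed about as widely as against wild type, with 2492 genes higher and 3109 lower than in lba1, and 2340 higher and 2945 lower than in upf3-1. FBA5 and AT2G10940 were among the lowest in both, at −7.52 and −7.12 from lba1 and −7.90 and −6.71 from upf3-1. AT1G66100 stood at 66.0 RPKM in lba1, 107 in upf3-1 and 0.053 in lba1 upf3-1. The gibberellin-regulated gene GASA6 was at −7.48 from lba1, and RGF9, a root growth peptide gene, and AT3G06070 at −7.04 and −6.59 from upf3-1. Among the highest were PR1 (12.11 from lba1), AT1G26390 (8.39 and 7.10), ARD3 (7.72 from upf3-1) and TI1 (8.30 from lba1).

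Of the 947 genes higher in at least 1 single mutant, 616 were higher and 108 lower in lba1 upf3-1. For lba1 and lba1 upf3-1, 427 genes were higher in both (148 for independent lists) and 57 lower in both (57.7), while 137 were lower in lba1 and higher in lba1 upf3-1 (59.99) and 83 the reverse (143), with r = 0.19 and a covariance of 0.172 (simulated r = 0.518 and 0.00175). For upf3-1 and lba1 upf3-1, 388 were higher in both (118) and 61 lower in both (16.3), while 3 were lower in upf3-1 and higher in lba1 upf3-1 (17.0) and 47 the reverse (114), with r = 0.44 and a covariance of 0.337 (simulated 0.523 and 0.00176). With no column in common, lba1 against wild type and lba1 upf3-1 against upf3-1 had r = 0.07, and upf3-1 against wild type and lba1 upf3-1 against lba1 had 0.29. How much of the excess over the simulated covariance stems from the shared column cannot be told. The lower r without a shared column does not settle this, because changing the partner also takes out what the single mutants have in common.

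A set of 199 genes was at least 2-fold higher in all 3 mutants, where independent lists would share 5.64, and non-coding RNAs and annotated pseudogenes made up an outsized part of it. Because all 3 comparisons use the same wild type column, error in that column alone could place genes in such a set. Numbers for independent lists do not allow for this, and unchanged groups were not simulated for sets of 3. Among genes chosen after the values were seen, the non-coding RNA AT3G26612 was at 3.19 RPKM in wild type, 24.1 in lba1, 23.8 in upf3-1 and 65.1 in lba1 upf3-1. AT1G11175 was at 6.98, 38.9, 48.4 and 79.3 RPKM in the same order. JAX1, a lectin gene of virus resistance, had log2 differences of 2.38, 2.56 and 3.17, the pseudogene SADHU1-3 2.26, 2.27 and 2.45, and CPUORF47, a gene with a conserved upstream open reading frame, 2.35, 2.22 and 2.35. The non-coding RNAs AT2G32795, AT5G38005 and AT2G45023 were at 3.04, 4.17 and 3.99 in lba1 upf3-1.

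The set held 158 of 13804 protein-coding genes (1.14%), 21 of 78 non-coding RNAs (26.9%) and 19 of 92 annotated pseudogenes (20.7%), a class in which the reference does not separate transposon genes. Genes low in wild type could pass the 5 RPKM filter through the mutant columns, which can raise such shares. Shares by wild type level were not computed. The median log2 difference of the set was 1.47 in lba1, 1.43 in upf3-1 and 2.34 in lba1 upf3-1, whose column was above both single mutants for 170 of the genes. With cycloheximide its median was −0.05, against −0.81 for all described genes, with 45 of the 199 higher and 38 lower than in mock, where 13.3% of protein-coding genes were higher and 44.1% lower. The 10 genes lower in all 3 mutants (0.316 for independent lists) were PDF1.2, PDF1.2c, GER3, the sugar transporter gene SWEET1, AT1G53541, the nicotianamine synthase gene NAS4, AT3G06019, AT3G16670, AT4G15700 and scpl35. GER3 was at −1.37, −1.60 and −6.91, NAS4 at −1.02, −1.70 and −2.57, and scpl35 at −1.39, −1.07 and −1.11 in lba1, upf3-1 and lba1 upf3-1.

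Taken class by class, 29 of 78 non-coding RNAs (37.2%) were higher in lba1, against 4.36% of protein-coding genes and a median of 4 in random sets of matched expression (range 1 to 8). In upf3-1 the number was 30 (38.5%; random 0 to 6) and in lba1 upf3-1 41 (52.6%; random 10 to 24). Annotated pseudogenes were higher in 29 of 92 cases in lba1 (31.5%; random 1 to 9), 28 in upf3-1 (30.4%; random 0 to 6) and 39 in lba1 upf3-1 (42.4%; random 13 to 28). With cycloheximide 10 non-coding RNAs (12.8%) and 16 of 92 pseudogenes were higher, inside the random ranges of 5 to 16 and 6 to 18. In mock 7 non-coding RNAs were higher (random 5 to 16) and 19 pseudogenes (random 6 to 18). The filter and the matching used the mean over all 6 columns, so genes high only in mutants could enter each class.

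**Figure D2:**
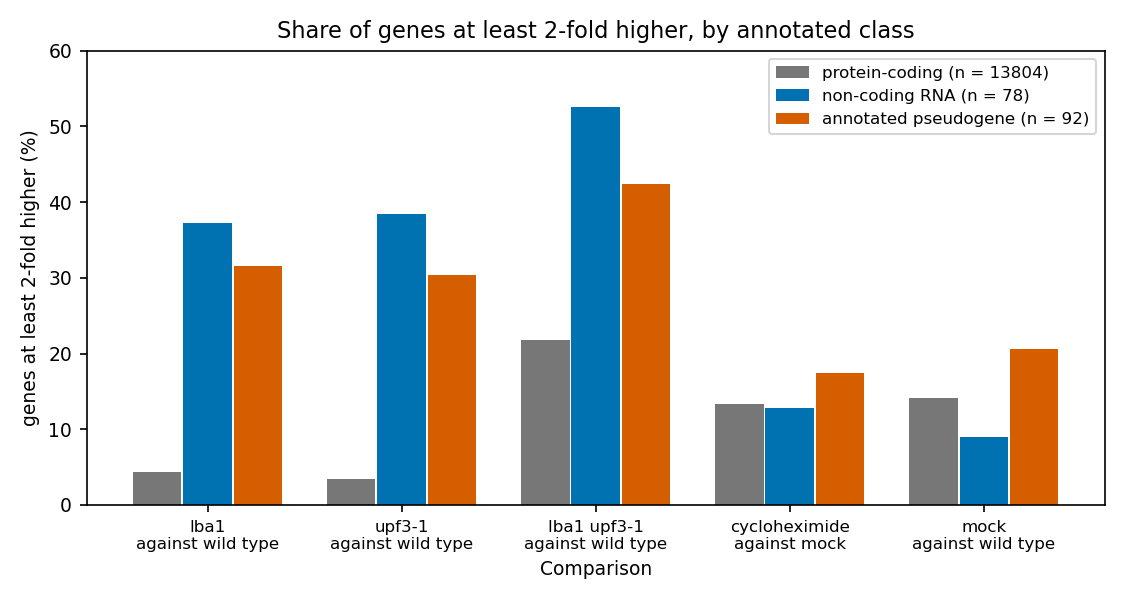
Percent of genes at least 2-fold higher (vertical axis, from 0) in each of 5 comparisons, as 1 bar per gene class: 13804 protein-coding genes, 78 non-coding RNAs and 92 annotated pseudogenes. In lba1 and upf3-1 the bars of non-coding RNAs reach 37.2% and 38.5%, against 4.36% and 3.44% for protein-coding genes, whereas with cycloheximide they reach 12.8% against 13.3%.

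Mock seedlings spent 4 h in liquid medium without the drug. The medians of heat shock genes and early stress transcription factors were higher than in untreated seedlings, and those of photosynthesis and cell cycle genes were lower. The iron deficiency median was lower as well, in a list drawn up after its leading genes had been noticed. All 12 heat shock genes were higher, with a median of 3.52 above every random list (range −0.48 to 0.59), HSP17.6A among them at 32.9 against 0.464 RPKM. Early stress and wound transcription factors had 14 of 22 higher and a median of 1.97, also above every random list (range −0.44 to 0.70). In all, 1996 genes were higher and 1677 lower, 26.1% of those described, but 1678 and 2017 after median scaling and 1725 and 2115 under quantile normalization, so that the direction with more genes turned.

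The highest genes were AT5G55150 (142 against 0.599 RPKM, 7.02), AT5G24640 (115 against 0.400 RPKM), AT2G41730 (6.60), AT4G12735 (6.59) and AT2G18193 (586 against 6.88 RPKM). The lowest were BHLH100 (−5.96), PR1 (−5.90), AT1G13609 (−5.69), the iron transporter gene IRT1 (0.102 against 25.1 RPKM) and AT2G30766 (−5.29). Ribosome biogenesis (1.18, 5 of 8 higher), endoplasmic reticulum stress (1.29, 6 of 10) and early auxin genes (0.75, 10 of 24) were above their random lists. Photosynthesis (−0.84, 13 of 30 lower), cell cycle (3 of 6 lower, range −0.68 to 0.64) and salicylic acid defence genes (−0.33, 6 of 24) were below them. The other 9 lists lay inside, with medians of 0.47 for NMD factors, 0.33 for splicing regulators, 0.53 for jasmonate signalling, 0.19 for ribosomal proteins, 0.64 for hypoxia, −0.42 for root markers and −0.19 for the clock. Those of uORF genes (0.32) and NLR receptors (0.23) changed sign under quantile normalization. Median scaling removed a shift of 0.13.

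The mock and lba1 upf3-1 effects overlapped, with 1073 genes higher in both (440.2 for independent lists) and 1202 lower in both (356). Their log2 differences had r = 0.54 and a covariance of 0.983, against 0.510 and 0.00173 for simulated unchanged groups. Where lba1 or upf3-1 replaced wild type as the partner of lba1 upf3-1, so that no column was shared, r was 0.52 in each case.

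With cycloheximide, early stress, jasmonate and defence transcripts were far above mock, and ribosomal protein and chaperone transcripts were far below it. ERF13, an ethylene response factor gene, was at 1055 RPKM against 1.47 in mock (log2 9.07), and BHLH92 at 956 against 0.975 (9.34). LTP2, a lipid transfer protein gene, was at 0.503 against 264 RPKM (−8.04). By the 2-fold rule 1870 genes were higher and 6209 lower, 57.4% of those described. The median of the described genes lay low, although the summed RPKM of the column was above that of mock. Median scaling removed a shift of −0.73 and gave 3075 higher and 3299 lower genes. The share higher became 48.2% in place of 23.1%, with 46.9% under quantile normalization. List medians are given as deposited and, where scaled values stand beside them, after removal of the shift of −0.73. The ranges of random lists are unscaled, so only the median as deposited can be set against them.

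GH3.1 was at 336 RPKM against 0.393, ORA47 at 645 against 1.34 and RRTF1, a redox-responsive factor gene, at 1025 against 2.63, with log2 differences of 8.56, 8.46 and 8.35. AT1G30190 (8.77), AT5G21960 (8.24) and AT1G68250 (8.19) were the other highest genes. The lowest after LTP2 were AT1G09310 (2.64 against 674 RPKM), AT5G42530 (−7.33), the lipid transfer protein genes LTP5 (−7.21) and LP1 (−7.02), the dehydration-responsive gene RD22 (−7.11), AT2G25510 (−6.85) and the cold-regulated gene COR15A (1.29 against 190.0 RPKM).

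All 22 genes of the early stress and wound list were higher, with a median of 3.60 (4.33 scaled) above every random list (range −2.28 to −0.21). ERF6 was at 957 against 14.4 RPKM, ERF11 at 469 against 4.69 and CBF2 at 5.46. Jasmonate signalling genes had 15 of 19 higher and 3 lower (median 3.32, scaled 4.05, range −2.33 to −0.17), with the repressor genes JAZ7 at 7.71 and JAZ8 at 6.16 and the lipoxygenase gene LOX3 at 5.55. Salicylic acid defence genes had 18 of 24 higher and 3 lower (median 3.06, scaled 3.79, range −1.60 to −0.23), among them the regulator genes SARD1 (6.39) and CBP60G (5.81) and WRKY46 (6.37), while PR1 was lower (−1.80). NLR receptors had 16 of 27 higher and 1 lower (median 1.23, range −1.40 to −0.23), or 19 higher and 0 lower after scaling, with WRR4 at 3.45, RPM1 at 2.49 and RPS6 at 2.68. Early auxin genes had 8 of 24 higher and 3 lower (median 0.47, range −1.32 to −0.04), or 13 higher and 2 lower after scaling with a median of 1.2, with IAA6 at 105 against 1.06 RPKM and GH3.3 at 2.93.

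All 28 ribosomal protein genes were lower, with a median of −3.33 (−2.59 scaled) below every random list (range −2.19 to −0.36). RPL9D was at −4.39 and RPL28A at −4.19. Ribosome biogenesis genes had 7 of 8 lower (median −3.72, scaled −2.99, range −2.21 to 0.41), with NOP58-1 at −5.56 and FIB2 at −5.02. Endoplasmic reticulum stress genes had 9 of 10 lower (median −4.14, scaled −3.41, range −2.33 to 0.52). The luminal chaperone genes BIP1 and BIP2 were at 2.27 and 3.78 RPKM against 254 and 262, and BZIP60, the exception, was higher (2.23). Hypoxia (−3.46, scaled −2.73, range −1.73 to 0.21, 7 of 11 lower and 1 higher), heat shock (−2.61, scaled −1.88, range −1.62 to 0.13, 11 of 12 lower) and root marker lists (−1.38, scaled −0.65, range −1.03 to 0.25, 8 of 14 lower and 5 after scaling) were also below their random lists, with LBD41 at −4.51, HSP90.1 at −4.67 and NRT2.1 at −3.99.

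The clock list had a median of 0.01, above its range of −1.63 to −0.05, a mean of −0.12 and a scaled median of 0.74. It had 2 genes higher and 4 lower, or 4 and 1 after scaling, from CHE at 2.70 to LNK1 at −1.96. Lists inside their ranges were photosynthesis (−1.75, scaled −1.02, −2.57 under quantile normalization, 28 of 30 lower and 16 after scaling), splicing regulators (−1.09, scaled −0.36, 18 of 30 lower and 4 after scaling, with RS31A higher at 1.66) and NMD factors (−0.96, scaled −0.23, 5 of 11 lower and 0 after scaling). The uORF list (−0.39) and the cell cycle list (−0.70) were inside as well, and both changed sign with scaling, to 0.34 and 0.03. The value of −0.60 for UPF1 became 0.13 with median scaling and 0.01 under quantile normalization. Among the uORF genes CIPK6 was at −2.84 and AT5G45430 at 2.07.

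**Figure D3:**
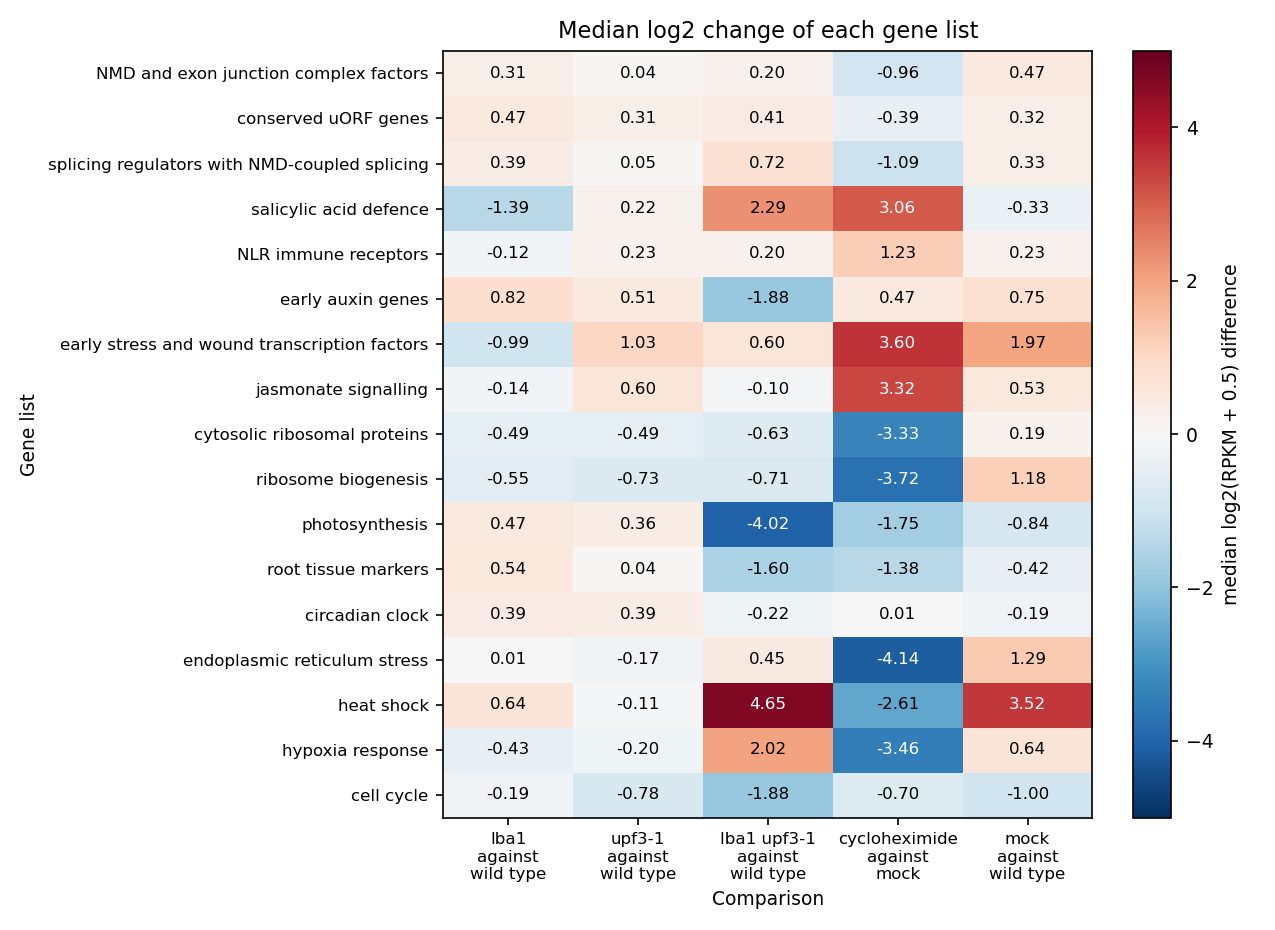
Heat map of the median log2 difference of 17 gene lists in 5 comparisons, with the colour scale running from −5 to 5 and no column scaling applied. Photosynthesis is at −4.02 and heat shock at 4.65 in lba1 upf3-1, and with cycloheximide early stress factors are at 3.60 and ribosomal proteins at −3.33.

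Cycloheximide and lba1 upf3-1, whose controls are different columns, shared more genes than independent lists of their sizes would. Higher in both were 806 genes (412 for independent lists), led by AT1G68250 (6.23 in lba1 upf3-1 and 8.19 with cycloheximide), WRKY38 (5.39 and 5.96), the pseudogene AT3G48650 (6.22 and 5.59) and EM1, a late embryogenesis gene (4.97 and 5.18). AT5G24200 and AT3G13433 followed. Lower in both were 1619 genes (1318), led by GER3 (−6.91 and −5.19), AT5G22580, CAD9, GAMMA-TIP, a vacuolar aquaporin gene (−4.42 and −6.38), AT3G62550 and COR15B. Genes in opposite directions were 256 and 1005, against 397 and 1369 for independent lists. Across genes r was 0.22 and rho 0.21. With lba1 the cycloheximide effect had r = 0.06, with 137 genes higher in both (89.3 for independent lists) and 124 higher with cycloheximide but lower in lba1 (36.1). With upf3-1 it had r = 0.32, with 230 genes higher in both (71.2) and 10 higher with cycloheximide but lower in upf3-1 (10.2).

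Taking the lba1 upf3-1 effect from the cycloheximide effect left 2649 genes at least 2-fold above it and 6418 below, or 29.2% above, which became 54.1% once median scaling removed a shift of −0.87 and 50.4% under quantile normalization. The furthest above were ERF13 (10.39), GH3.1 (9.01), ORA47 (8.97), AT2G20350 (8.18) and the methyltransferase gene FAMT (7.96). The furthest below were AT3G02480 (−11.69), the protease inhibitor gene UPI (−11.09), LTP2 (−10.56), HSP17.4 (−10.01) and AT3G63380 (−10.00). HSP17.4 was thus at 182 RPKM in lba1 upf3-1, 26.7 in mock and 3.44 with cycloheximide, each above its level in untreated wild type.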

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

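No paired analysis was possible because each group is represented by 1 column that carries no replicate number. For the same reason the fits with a block, with only the compared groups, with robust estimates or without each library, and the list tests with an estimated correlation or with fry, were not run. The filters at 0.5 and 20 RPKM, the 4-fold rule, and the list medians at a pseudocount of 0.1 and under quantile normalization were chosen after seeing the data.

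The pseudocounts of 0.1 and 1 RPKM, the filter at 2 RPKM, median scaling and quantile normalization kept each total of genes past 2-fold, and the shared total, within 1.5 times. The split into higher and lower moved more. With median scaling, cycloheximide went from 1870 higher and 6209 lower to 3075 and 3299, and the difference of effects from 6418 below to 3671. Under quantile normalization upf3-1 went from 77 lower to 167. With no filter the totals were 1507 for lba1, 9747 for lba1 upf3-1, 9172 for lba1 upf3-1 against lba1, 8279 for it against upf3-1 and 13880 for the difference between the cycloheximide and lba1 upf3-1 effects. With a filter at 0.5 RPKM the first 3 were 1468, 9317 and 8744. More genes enter by construction. At 20 RPKM fewer enter, and the totals were 352 for lba1, 287 for upf3-1, 2466 for lba1 upf3-1, 3502 for cycloheximide, 425 for lba1 against upf3-1, 2454 and 2205 for lba1 upf3-1 against lba1 and upf3-1, 1761 for mock, 3539 for the difference of effects and 1210 for shared genes. With the stricter 4-fold rule they were, in the same order, 110, 42, 2687, 3542, 150, 2554, 2204, 956, 4732 and 690.

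Of 815 differences past 2-fold of named genes, the direction held in 815 with either pseudocount and with median scaling, and in 812 under quantile normalization. The exceptions were cycloheximide against mock for NATA1 (0.043), SADHU1-3 (0.058) and AT3G01570 (0.21), and the cause was not tested. Differences still past 2-fold numbered 815 at a pseudocount of 0.1, 772 at 1, 723 with median scaling and 738 with quantile normalization. List medians, 85 in all, stayed close to their values in 81 cases at a pseudocount of 0.1, 84 at 1, 79 with median scaling and 74 under quantile normalization. Early auxin genes went to −2.82 in lba1 upf3-1 at a pseudocount of 0.1 and to 1.2 with cycloheximide under median scaling, and conserved uORF genes in upf3-1 to 0.00 under quantile normalization. Depth limits little at 5 RPKM, and the lack of replicates limits every comparison.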

Other observations

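Of the tests in this part, those on twin loci, seed material, heat stress and cycloheximide were chosen only after the result was seen, whereas those on overlapping exons, iron and phosphate were written down before. Most genes of the iron deficiency response were lower in upf3-1, lba1 upf3-1 and mock. The list of 13, drawn up after its leading genes had been noticed, had medians of −0.25 in lba1, −1.66 in upf3-1, −2.57 in lba1 upf3-1 and −2.45 in mock against wild type, and 0.21 with cycloheximide against mock. FRO2, the root iron reductase gene, was at 9.29 RPKM in wild type, 4.91 in lba1, 1.35 in upf3-1, 0.389 in lba1 upf3-1 and 0.143 in mock. The 7 members whose values had not been seen when they were listed had a median of −0.59 in upf3-1, with 6 below wild type, where random lists ranged from −0.29 to 0.42. This is close to the bound set for it, and in line with a lower iron deficiency response as a group in that column.

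Phosphate starvation genes were lower in lba1 and not in upf3-1, with medians over 12 genes of −1.69 and 0.23, then −0.08 in lba1 upf3-1, −0.43 in mock and 0.93 with cycloheximide. The phosphatase gene PS2 was at 5.86 RPKM in lba1 against 45.0 in wild type, and SPX1, a phosphate sensor gene, at 24.7 against 74.0. The 8 members not seen when listed were all below wild type in lba1, at a median of −1.44 and a random range of −0.30 to 0.37, in line with a lower response as a group. Small nucleolar RNAs were lower with cycloheximide in 20 of 21 cases, at a median of −4.15, in libraries that sample such RNAs poorly.

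Seed maturation genes were higher in lba1 and lba1 upf3-1 but not in upf3-1, with medians over 12 measured genes of 2.04, 4.48 and 0.11, and of −0.35 in mock and 0.04 with cycloheximide, but the values of all but 2 of these genes had been seen when they were listed. The most abundant, the cruciferin gene CRA1, was at 14.3 RPKM in wild type, 25.2 in lba1 and 181 in lba1 upf3-1, and OLEO1, of seed oil bodies, at 0.817, 5.25 and 41.5. Some small heat shock genes, also made in maturing seeds, were higher in the same columns and also in mock, where seed genes were not. HSP17.4 was at 3.78 in lba1, but HSP18.2 was at 0.23 there. A general heat stress in lba1 would put HSP101, HSP70 and HSP90.1 at least 2-fold higher, and their median of −0.84 goes against it. The whole heat shock list lay the other way, at 0.64 with 9 of 12 above 0. That list holds small heat shock genes that raised the question, and 3 genes are few, so a general heat stress was left open. For seed or embryo material of 1 composition in both columns, 45.5% of 11 genes had a ratio of gains within 2-fold of the median of 9.17. This crossed the bound written as going against that explanation. The exact binomial interval, 16.7% to 76.6%, spans the bound but treats the genes as independent. The reading of both tests was made more cautious after their values were known. The ratios ran from 0.582 to 30.1, a spread that also goes against 1 composition. Without replicates the spread to allow for is unknown, so seed material was not told apart from induced expression. No biological explanation beyond the mutant groups was tested.

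A part of the conserved uORF list was listed at 0 or near it in every column, including BZIP11 and other genes that seedlings are known to express. For 22 of the 42 members a neighbouring locus code had identical values, 6 of these pairs at 0 and 16 above it, and the 22 partners are missing from the reference table. Such twins occurred in 0.102% of the 25545 protein-coding loci above 0. Reads shared with a second locus for the same transcript that were left uncounted are a candidate explanation. The values of those members may then understate their transcripts. The count of twins shows identical values and not lost reads, so it cannot decide whether reads were left uncounted. A loss of shared reads does not by itself account for identical values above 0 in 16 pairs. Of 330 loci with at least 90% overlap 14.5% were at 0, more than the 5.45% of 20160 loci without overlap. The ratio of 2.67 lay between the bounds set for it, so the test gave no verdict on a general loss of reads over overlapping exons. Other differences between these sets of loci were not tested.

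Ribosomal protein and chaperone transcripts were far lower with cycloheximide than in mock. Induced genes that take a larger share of the reads would lower other genes alike, but the ribosomal protein median lay at −2.51 relative to the median of all genes. A single shift of the scale of the column would also move all genes alike, so the same value argues against it. After median scaling 28 of 28 ribosomal protein genes, or 100%, were still at least 2-fold lower. With the highest of them at −2.30 and a shift of −0.73 this had to follow, so it is no separate argument. A drop of ribosomal protein transcripts relative to others during the treatment may be biological. This is a hypothesis found and tested on the same columns, without replicates. Chaperone genes did not enter either test, and gene length and composition were not tested.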
